A study of Mus musculus with 12 samples.

How the data were processed

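The series measured messenger RNA in gonadal somatic cells of mouse embryos. The cells carried a green fluorescent protein under control of the Sf1 (Nr5a1) promoter and were collected by fluorescence-activated sorting of the green cells, per the labels. There were 12 samples in 4 groups of 3: females and males at 10.5 days post coitum (dpc) and females and males at 11.5 dpc. Per the labels the RNA went through 2 rounds of amplification and was labelled with biotin, and each sample was read on its own Affymetrix mouse array. Ages, sexes and replicate numbers were taken from the sample titles.

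The deposited values are intensity values on a linear scale, 1 per probe set and array, and were made by the authors with RMA (robust multi-array average: background correction, quantile normalization and a summary over the probes of a probe set), per the submitters' processing notes, which give no version. RMA usually ends in log2 values, and no source used here says how the linear scale was reached. The deposited table held 45101 probe sets with array medians from 41.21 to 43.88 and array maxima from 78847 to 86711.7. Quantile normalization gives all arrays nearly the same distribution of values, so a change shared by most transcripts cannot be seen in such a table. RMA also pulls dim probe sets together, so fold changes of genes near the lowest intensities are understated. No detection calls were used, and the number of arrays limits the precision.

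The 64 Affymetrix control probe sets were left out of the tests and described apart, and 45037 probe sets were tested. The plan made before the data were examined had assumed log2 values; the values are linear, so intensities were turned into log2(value + 1), and fold changes are on that scale, which understates the change of dim genes. Linear models with 1 mean per group were fitted to all 12 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit, contrasts, eBayes), with 8 residual and 1.89 prior degrees of freedom. All 4 groups shared 1 estimate of the spread. The 5 contrasts were male minus female at 10.5 dpc, male minus female at 11.5 dpc, 11.5 minus 10.5 dpc in females, 11.5 minus 10.5 dpc in males, and the male age change minus the female age change. The p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Adjusted p-values of genes are from limma throughout. Errors after a log2 change are standard errors (SE) of the contrast, with n = 3 arrays per group.

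Nothing in the labels says that the 3 samples of a group came from separate animals or pools, so the p-values measure only the spread between these arrays, which may be technical. Within groups the arrays correlated with r from 0.9981 to 0.9988 across probe sets, and the median SD of a probe set within a group was 0.0557 to 0.0617 on the log2 scale. That spread is small, so changes of a few percent passed the threshold, and counts of changes of at least 2-fold are given beside the counts of all calls.

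Probe sets were named from the platform annotation, which is old. Of the tested probe sets, 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 had none there. Symbols were updated through Entrez gene identifiers with the RefSeq gene table of assembly GRCm38.p6, which 34741 probe sets matched. No coordinates are given because the build behind the array annotation is not given in the sources used here. A gene was represented by the probe set with the highest mean over the 12 arrays among those that name it alone, and by a probe set of the cross-hybridising kind only where there was no other, which gave 18193 genes. Where other probe sets of a gene gave an opposite call, this is said beside the gene.

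In the same plan 26 gene lists with 397 genes were fixed, of which 360 had a probe set of their own. They covered testis determination and Sertoli cells, ovary and pregranulosa cells, genital ridge factors, steroidogenesis, cholesterol synthesis, interstitial progenitors, Y-linked genes, X inactivation and escape, germ cells, endothelium, erythroid cells, macrophages, nephric duct and tubule epithelium, coelomic epithelium and mesothelium, neural and neural crest cells, skeletal muscle and somite, cell cycle, cell cycle inhibitors, extracellular matrix, glycolysis and hypoxia, immediate early and dissociation stress genes, Hox genes, hedgehog and Notch targets, Wnt and BMP targets, FGF targets, and retinoic acid metabolism and response. For each list the genes past the threshold were counted, both over all probe sets and adjusted over the list alone. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 26 lists of a contrast. Camera with an estimated correlation between genes was the main alternative. Adjusted p-values of lists are from camera.

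The genes named were also fixed there by rule. For each comparison they were the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap (for the difference between the age changes, past the threshold), up to 4 genes past the threshold with the smallest p from each list (or up to 2, given as values, where none passed), and always Nr5a1, Xist, Eif2s3y, Sry and Sox9. The rule also named Ddx3y, which had no probe set of its own in the annotation used and is not analysed here.

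Alternatives were the replicate number as a block, a filter on probe sets at or above the median intensity of 42.6 in at least 3 arrays, a further quantile normalization, centring each array on its median, a fit of only the groups compared, eBayes with trend and robust settings, array weights, leaving out cross-hybridising probe sets, averaging the probe sets of a gene, stricter thresholds, a pseudocount of 16 and leaving out each array in turn. After the data had been seen, a split of the arrays by the hybridisation controls and a one-sided Fisher's exact test of 2-fold changes in each list were added. The procedure was tested on simulated arrays with the real means and spreads of 45037 probe sets and independent noise. Changes were given to 200 probe sets, all from those at or above the median intensity. For the sex difference at 10.5 dpc it recovered 68% of changes of 0.5 and 92% of changes of 1 on the log2 scale, and 5.88% of calls were false. For the difference between the age changes the shares were 43% and 86%, with 5.84% false calls. The real comparisons called 28.1% to 46.7% of probe sets, so these shares do not carry over to them, nor to dimmer probe sets. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.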

Results

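RNA levels were measured in sorted Sf1-positive somatic cells of the mouse gonad at 10.5 dpc, when the genital ridge has the same form in both sexes, and at 11.5 dpc, when the sexes begin to part. The design addressed 2 questions: how expression changed over this day, and which genes differed between the sexes. Each age and sex had 3 arrays. Arrays of the same group were nearly identical, arrays of the 2 sexes at the same age correlated with r from 0.9886 to 0.9899, and arrays of the 2 ages in the same sex with r from 0.9755 to 0.9794, across probe sets. Errors given with log2 changes are standard errors (n = 3 arrays per group), and the number of arrays limits the precision.

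Sex-linked transcripts separated the labelled sexes at both ages. Xist (probe set 1436936_s_at), the noncoding RNA that silences an X chromosome in females, had a mean intensity of 6960 in females and 27.6 in males at 10.5 dpc, and of 8350 and 11.5 at 11.5 dpc. Among 7 measured Y-linked genes, 4 were higher in males at each age (4 adjusted over the list alone), with camera adjusted p = 0.0017 at 10.5 dpc and 0.0038 at 11.5 dpc. They had an adjusted p = 0.12 and an adjusted p = 0.11 with an estimated correlation. Eif2s3y (1417210_at), a translation factor subunit, was higher in males by 7.79 ± 0.14 (SE) at 10.5 dpc and by 4.61 ± 0.14 at 11.5 dpc on the log2 scale. The demethylase gene Kdm5d was higher by 5.79 ± 0.12 and 4.79 ± 0.12, and Uty by 5.35 ± 0.13 and 5.11 ± 0.13. Eif2s3y stood at a mean intensity of 9.8 ± 2.56 (SD, n = 3) in females at 10.5 dpc and 64.7 ± 4.07 in females at 11.5 dpc, against 1610 ± 59.2 in males at 11.5 dpc. The probe set of Sry (1450578_at), the Y-linked testis-determining gene, read near the lowest intensities in every group, from 6.46 to 7.67. Its signal did not pass between the sexes at 10.5 dpc (0.02 ± 0.093, adjusted p = 0.91) or at 11.5 dpc (-0.2 ± 0.093, adjusted p = 0.13). Females lack the gene, so a signal no higher in males is background and says nothing on Sry expression. Nr5a1 (1418315_at), the gene behind the sorting marker, was higher in males by 0.73 ± 0.051 at 10.5 dpc and by 0.45 ± 0.051 at 11.5 dpc.

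At 10.5 dpc the largest sex differences outside the sex chromosomes were mostly genes higher in females, among them genes known from neurons, stem cells, blood vessels and blood. The neural transcription factor genes Zic1 (1423477_at) and Hmx1 were lower in males by -4.42 ± 0.4 and -3.71 ± 0.22 on the log2 scale. The neuronal tubulin Tubb3 was lower by -3.34 ± 0.12 and the stem cell factor Sox2 by -3.24 ± 0.072. Of 12 measured genes of the neural and neural crest list, 8 were lower in males and none higher (8 and 0 adjusted over the list alone), with a median of -1.25 and camera adjusted p = 0.00074. Of 17 germ cell genes, 14 were lower in males (14 adjusted over the list alone), with a median of -1.29 and camera adjusted p = 2.1e-06. Among them were the pluripotency gene Pou5f1 (-2.39 ± 0.12) and Dppa5a (-2.19 ± 0.069). Sox2, a member of that list, is also expressed in neural tissue. Of 15 endothelial genes, 11 were lower in males (11 adjusted over the list alone), with a median of -1.2 and camera adjusted p = 0.00079. Examples were Cldn5, a tight junction protein of vessels (-2.67 ± 0.24), and the transcription factor Erg (-2.22 ± 0.19).

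Other groups moved less at this age. Of 30 Hox genes, which encode positional transcription factors, 15 were lower and 2 higher in males (16 and 2 adjusted over the list alone), with a median of -0.28 and camera adjusted p = 0.0043. Hoxb6 (-1.73 ± 0.056) and Hoxd9 (0.51 ± 0.041) lay on opposite sides. Genital ridge factors went the other way, with 10 of 16 higher and 2 lower in males (10 and 3 adjusted over the list alone) and camera adjusted p = 0.015. Their list had an adjusted p = 0.12 with an estimated correlation. Gata4 (1 ± 0.041), a regulator of early gonad growth, and the Notch regulator Numb (0.89 ± 0.046) were among them. The embryonic globins Hbb-y, Hba-x and Hbb-bh1 were lower in males by -2.97 ± 0.052, -2.34 ± 0.065 and -2.19 ± 0.062. Of the 12 erythroid genes 4 were lower in males (4 adjusted over the list alone), 8 did not pass, and the list did not pass (camera adjusted p = 0.055).

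The testis and ovary lists did not pass at 10.5 dpc. In the testis list 4 of 22 genes were higher and 5 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.83), with a median of 0, a mean of -0.01 and an upward test direction. Map3k4, a kinase needed for Sry expression, stood at 1.38 ± 0.051. In the ovary list 2 of 20 were higher and 8 lower (2 and 8 adjusted over the list alone, camera adjusted p = 0.28). At least 2-fold, 4 of the 20 were lower and 0 higher, against 549 and 251 of all 18193 genes. Wnt4 (1450782_at), an ovary-promoting signal, stood at 0.75 ± 0.05 and the homeobox gene Irx3 at -1.9 ± 0.14. Sox9 (1424950_at), which drives Sertoli cell formation, was lower in males by -0.86 ± 0.12. Of its 3 probe sets 1 gave the opposite call, and the mean of the 3 (-0.26) did not pass. Of 13 nephric duct and tubule epithelium genes 1 was higher and 6 lower (1 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.1). The epithelial adhesion genes Cdh1 and Epcam stood at -2.09 ± 0.096 and -2.05 ± 0.12. Further lists of other cell types that did not pass were macrophages (0 of 15 higher, 5 lower, 1 and 6 adjusted over the list alone, camera adjusted p = 0.14) and skeletal muscle and somite (0 of 12 higher, 3 lower, 0 and 3 adjusted over the list alone, camera adjusted p = 0.055). Coelomic epithelium and mesothelium genes (2 of 10 higher, 3 lower, 3 and 3 adjusted over the list alone, camera adjusted p = 0.77) and cell cycle inhibitors (0 of 10 higher, 6 lower, 1 and 6 adjusted over the list alone, camera adjusted p = 0.064) did not pass either.

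In all, limma called 15371 of 45037 probe sets at 10.5 dpc, 8045 higher and 7326 lower in males, or 52.3% higher, which became 49% with each array centred on its median. Counted in genes the balance was the other way, with 3293 higher and 4128 lower. A change of at least 2-fold was seen for 251 genes higher and 549 lower in males. With an estimated correlation the germ cell, endothelial, neural and Hox lists still passed (adjusted p = 0.011, 0.027, 0.027 and 0.034). A measure of RNA quality or amplification differed between the same groups. The ratio of the 3′ to the 5′ control probe set for actin was 5.32 ± 0.12 (SD, n = 3) in females at 10.5 dpc and 9.9 ± 0.022 in males at 10.5 dpc. It was 9.97 ± 0.12 in females at 11.5 dpc and 7.59 ± 0.16 in males at 11.5 dpc. For Gapdh it was 2.7 ± 0.1 in females and 4.65 ± 0.11 in males at 10.5 dpc.

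At 11.5 dpc the genes of the testis pathway were higher in males and those of the ovary pathway higher in females. Fgf9 (1438718_at), a growth factor needed for testis formation, was higher in males by 3.09 ± 0.072 on the log2 scale, and Cst9 (1449285_at), a cystatin of fetal Sertoli cells, by 4.81 ± 0.11. The collagen gene Col9a3 was higher by 3.92 ± 0.11 and the Sertoli cell signal Dhh (1434959_at) by 3.52 ± 0.14. Of 22 measured genes of the testis list, 14 were higher and 2 lower in males (14 and 2 adjusted over the list alone), with a median of 0.81 and camera adjusted p = 4.2e-07. Of 20 genes of the ovary list, 16 were lower and 1 higher in males (16 and 1 adjusted over the list alone), with a median of -0.69 and camera adjusted p = 1.9e-05. Sprr2d (-3.46 ± 0.13), the Wnt pathway activator Rspo1 (-1.43 ± 0.063) and Wnt4 (-0.91 ± 0.05) were lower in males. The exception was Lgr5 (1450988_at), a receptor for R-spondins, higher in males by 2.84 ± 0.13.

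**Figure D1:**
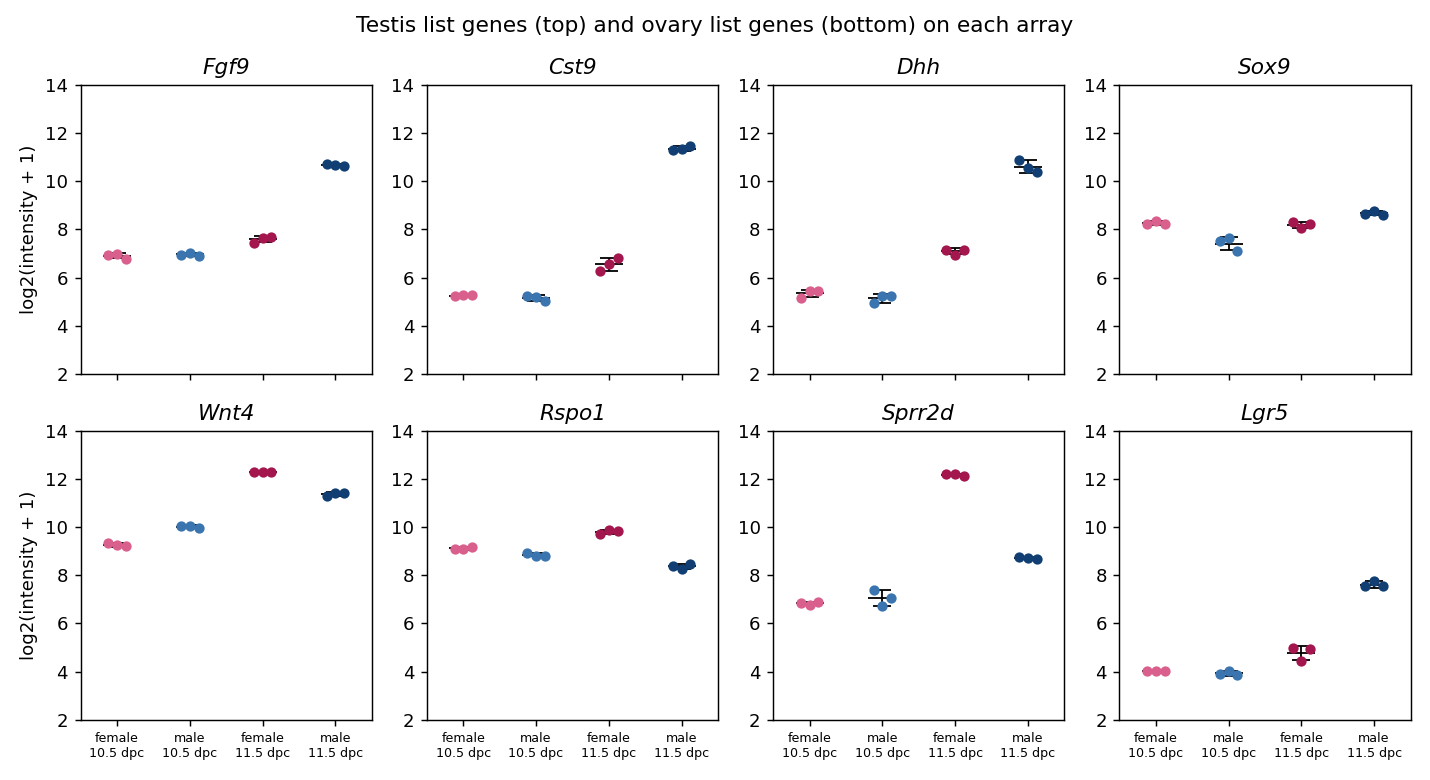
Level on the log2(intensity + 1) scale (vertical axis) of 4 genes of the testis list (top) and 4 of the ovary list (bottom) in the 4 groups (horizontal axis); points are the 3 arrays of a group, and bars show the mean and SD. Fgf9, Cst9 and Dhh part between the sexes at 11.5 dpc by 3.09, 4.81 and 3.52, while Sox9 does so by 0.48.

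Outside these lists and the sex chromosomes the largest differences at 11.5 dpc included Hcrtr1 (1436295_at), an orexin receptor, higher in males by 5.07 ± 0.1, the neurotrophic factor Gdnf by 3.97 ± 0.16 and alpha-fetoprotein (Afp) by 3.74 ± 0.23. Hcrtr1 lay near the lowest intensities in females (6.62 ± 1.33, SD) and at 252 ± 12.3 in males. Genes higher in females included Ugt2b36 (-3.99 ± 0.099), a glucuronosyltransferase, lipocalin 2 (Lcn2, -3.34 ± 0.12) and Tph2 (-2.86 ± 0.18), an enzyme of serotonin synthesis. Sox9 was higher in males by 0.48 ± 0.12 (adjusted p = 0.011).

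Genes of the extracellular matrix and of cholesterol synthesis were also higher in males at this age. Of 21 cell cycle genes, 15 were higher and 1 lower in males (15 and 2 adjusted over the list alone), with camera adjusted p = 7.4e-08. The test gave an adjusted p = 0.059 with an estimated correlation. The replication licensing factor Mcm2 (1.29 ± 0.038) and the proliferation marker Mki67 (1.14 ± 0.038) were among them. Of 17 extracellular matrix genes, 14 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 7.4e-08). Col18a1, a basement membrane collagen, was higher by 1.92 ± 0.051 and Col4a2 by 1.04 ± 0.048. Of 15 cholesterol synthesis genes, 9 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0017), such as Sqle (0.73 ± 0.053). Glycolysis and hypoxia genes were split, 7 of 15 higher and 6 lower (7 and 6 adjusted over the list alone), and did not pass (camera adjusted p = 0.58, median 0.1, mean -0.04). Aldh1a1, which makes retinoic acid, was higher in males by 2.34 ± 0.05. In the retinoic acid list 3 of 12 genes were higher and 2 lower (3 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.58), with a median of -0.02 and a mean of 0.19.

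Signalling targets were split at 11.5 dpc. Of 8 FGF targets, 5 were higher and 2 lower in males (6 and 2 adjusted over the list alone), with camera adjusted p = 0.047. This became an adjusted p = 0.17 with an estimated correlation, and Etv5, an FGF-induced transcription factor, stood at 1.53 ± 0.079. Of 14 Wnt and BMP targets, 11 were lower and 2 higher (12 and 2 adjusted over the list alone), with camera adjusted p = 0.0019. This became an adjusted p = 0.11 with an estimated correlation. Id1 (-1.51 ± 0.054) and Smad6 (-1.11 ± 0.053), both induced by BMP, were lower. The hedgehog targets Ptch1 (1.1 ± 0.073) and Gli1 (1.2 ± 0.21) were higher in males, but their list did not pass (camera adjusted p = 0.3). Of 13 interstitial progenitor genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.02). The adjusted p = 0.086 with an estimated correlation did not pass. Of 8 genes of X inactivation and escape, 1 was higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.11 with an estimated correlation). Of 13 nephric duct genes, none were higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.11 with an estimated correlation). The steroidogenesis list did not pass (3 of 12 higher, 2 lower, 3 and 2 adjusted over the list alone, camera adjusted p = 0.58), with a median of -0.01 and an upward test direction. The germ cell, endothelial and neural lists did not pass at 11.5 dpc (camera adjusted p = 0.12, 0.58 and 0.59), and the neural median of -0.03 and mean of 0.03 differed in sign. Of 12 erythroid genes, none were higher and 5 lower in males, 3 of them at least 2-fold (0 and 6 adjusted over the list alone). That list did not pass (camera adjusted p = 0.054).

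The test called 15522 probe sets at 11.5 dpc, 7989 higher and 7533 lower in males. Counted in genes the balance was the other way, with 3513 higher and 3846 lower, and 323 genes were at least 2-fold higher and 297 at least 2-fold lower. The testis, ovary, extracellular matrix and cholesterol lists passed with an estimated correlation too (adjusted p = 0.0084, 0.019, 0.024 and 0.033). The 3′ to 5′ ratios went opposite ways at this age: for actin 9.97 in females and 7.59 in males, for Gapdh 3.88 ± 0.059 and 4.19 ± 0.006 (SD).

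In females, the day from 10.5 to 11.5 dpc brought a rise of both ovary and testis list genes and a fall of Hox genes. Wnt4 rose by 3.03 ± 0.05 on the log2 scale, the transcription factor gene Runx1 by 4.39 ± 0.086 and Sprr2d by 5.33 ± 0.13. Of 20 ovary list genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 3.8e-05). Of 22 testis list genes, 14 rose and none fell (14 and 1 adjusted over the list alone, camera adjusted p = 8.3e-05), such as the tescalcin gene Tesc (4 ± 0.16) and the growth factor Pdgfa (2.38 ± 0.1). Male material in the female 11.5 dpc samples, left open below, could add to rises of genes with high male levels. Cst9 went from 37.2 to 93.8 in females, against 2620 in males at 11.5 dpc. Pdgfa was higher in females (2500) than in males (1750) at 11.5 dpc. The largest rises were those of the transcription factor Nfix (6.26 ± 0.092), the kallikrein Klk1 (6.14 ± 0.27) and the uncharacterised transcript 6430710C18Rik (6.13 ± 0.21).

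The largest falls in females included those of genes of neurons and their progenitors. Neurod1, a neuronal transcription factor, fell by 7.51 ± 0.059 and Zic1 fell by 6.46 ± 0.4. Pou4f1, a factor of sensory neurons, fell by 4.75 ± 0.11 and the signal gene Shh fell by 4.28 ± 0.39. In the neural and neural crest list 7 of 12 genes fell and 1 rose (7 and 1 adjusted over the list alone), with camera adjusted p = 0.04. This became an adjusted p = 0.11 with an estimated correlation. Of 30 Hox genes, 19 fell and none rose (20 and 0 adjusted over the list alone, camera adjusted p = 0.00026), such as Hoxa9 (-2.2 ± 0.052). Of 21 cell cycle genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.18 and camera adjusted p = 6.5e-07. The result was an adjusted p = 0.087 with an estimated correlation. Bub1, a spindle checkpoint kinase, fell by 3.6 ± 0.065 and the replication clamp Pcna fell by 2.21 ± 0.043.

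Coelomic epithelium genes and Wnt and BMP targets passed in females with the preset correlation only. Of 10 genes of the coelomic epithelium and mesothelium list, 6 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.038). The list had an adjusted p = 0.11 with an estimated correlation. The keratinocyte and mesothelial factor Bnc1 fell by 2.95 ± 0.065, and the retinoic acid enzyme Aldh1a2 fell by 1.99 ± 0.064. Of 14 Wnt and BMP targets, 11 rose and none fell (11 and 0 adjusted over the list alone, camera adjusted p = 8.3e-05), with the Wnt feedback gene Nkd1 at 3.17 ± 0.13. They had an adjusted p = 0.087 with an estimated correlation. Cyp11a1, which starts steroid synthesis from cholesterol, rose by 3.06 ± 0.33, and Star, which brings cholesterol into mitochondria, rose by 1.37 ± 0.041. The ACTH receptor Mc2r fell by 2.64 ± 0.19. Of 12 steroidogenesis genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.064). Sox9 stood at -0.08 ± 0.12 (adjusted p = 0.73), and another of its probe sets gave a call of the opposite sign.

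Metabolic, blood and matrix lists also passed in females with the preset correlation only. Of 15 glycolysis and hypoxia genes, 10 fell and 3 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.04), and Ddit4, a stress-induced inhibitor of growth signalling, fell by 2.17 ± 0.044. The adjusted p = 0.24 with an estimated correlation did not pass. Of 12 erythroid genes 6 rose and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.03). This became an adjusted p = 0.1 with an estimated correlation. Of 17 extracellular matrix genes 11 rose and 5 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.028). The test gave an adjusted p = 0.2 with an estimated correlation.

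The test called 18800 probe sets for the age change in females, 9448 rising and 9352 falling. Counted in genes the balance was the other way, with 4201 rising and 4893 falling. A change of at least 2-fold was seen for 1091 genes that rose and 1334 that fell. Centring each array on its median moved the share of rising calls from 50.3% to 31.9%, with a shift of -0.0708 on the log2 scale for the typical probe set, and all 2425 genes changed at least 2-fold kept their direction and call. The testis, ovary and Hox lists passed with an estimated correlation (adjusted p = 0.015 for each). The measure of RNA quality or amplification moved with this comparison. In females the 3′ to 5′ ratio went from 5.32 at 10.5 dpc to 9.97 at 11.5 dpc for actin and from 2.7 to 3.88 for Gapdh.

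In males the same day brought rises of testis list genes. Cst9 rose by 6.21 ± 0.11 on the log2 scale, Col9a3 by 6.28 ± 0.11 and Tesc by 6.84 ± 0.16. Dhh rose by 5.47 ± 0.14 and Fgf9 by 3.72 ± 0.072. Of 22 testis list genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.51 and camera adjusted p = 2.4e-08. Sox9 rose by 1.26 ± 0.12. The largest rise was that of Afp (8.39 ± 0.23), followed by Nfix (6.92 ± 0.092), and the matrix protein gene Ogn rose by 6.15 ± 0.1.

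Ovary list genes rose in males too, with 11 of 20 up and 4 down (11 and 4 adjusted over the list alone, camera adjusted p = 0.0093). This became an adjusted p = 0.057 with an estimated correlation. Runx1 rose by 3.88 ± 0.086, Lgr5 by 3.69 ± 0.13 and Wnt4 by 1.37 ± 0.05. Among genital ridge factors 9 of 16 fell and 4 rose (9 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.1). The homeobox genes Emx2 and Lhx9, both needed for the early gonad, stood at -3 ± 0.039 and -1.46 ± 0.028. The largest falls in males were those of the guanylate-binding protein Gbp2b (-5.55 ± 0.076) and Neurod1 (-5.33 ± 0.059). Of 10 genes of the coelomic epithelium list 7 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.037), and Bnc1 fell by 3.57 ± 0.065. The adjusted p = 0.098 with an estimated correlation did not pass.

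Several signalling and matrix lists passed in males with the preset correlation only. Of 8 FGF targets, 7 rose and none fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.057 with an estimated correlation), such as the feedback inhibitor Spry4 (3.65 ± 0.16) and Etv5 (3.04 ± 0.079). Of 17 extracellular matrix genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.057 with an estimated correlation), with Col18a1 at 4.06 ± 0.051. Of 15 immediate early and dissociation stress genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.00023), such as Btg2 (2.11 ± 0.049). The result was an adjusted p = 0.098 with an estimated correlation. The Notch ligand Jag1 rose by 2.71 ± 0.049 and the retinoic acid-binding protein Crabp1 by 3.74 ± 0.042. Hedgehog and Notch targets rose in 7 and fell in 2 of 14 cases (7 and 2 adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.098 with an estimated correlation). Wnt and BMP targets rose in 9 and fell in 3 of 14 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0096, adjusted p = 0.14 with an estimated correlation).

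Lists of vessels, blood and cell division also passed in males with the preset correlation only. Of 15 endothelial genes 8 rose and none fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0011), among them Cd34 (3.44 ± 0.29) and Erg (2.38 ± 0.19). The adjusted p = 0.055 with an estimated correlation did not pass. Of 12 erythroid genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.057 with an estimated correlation), with Hbb-y at 3.66 ± 0.052. Cholesterol synthesis genes rose in 9 and fell in 2 of 15 cases (10 and 2 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.057 with an estimated correlation). Hox genes fell in 16 and rose in 3 of 30 cases (18 and 3 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.057 with an estimated correlation). Cell cycle genes fell in 16 and rose in 3 of 21 cases (16 and 3 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.19 with an estimated correlation). Glycolysis and hypoxia genes fell in 11 and rose in 1 of 15 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.098 with an estimated correlation).

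The test called 21040 probe sets for the age change in males, 9101 rising and 11939 falling. In genes 4318 rose and 5433 fell, and 1082 genes rose and 943 fell at least 2-fold. Centring each array on its median moved the share of rising calls from 43.3% to 27.9%, with a shift of -0.0494 for the typical probe set, and all 2025 genes changed at least 2-fold kept their direction and call. The testis list alone passed with an estimated correlation (adjusted p = 0.0038). In males the 3′ to 5′ ratio went from 9.9 at 10.5 dpc to 7.59 at 11.5 dpc for actin and from 4.65 to 4.19 for Gapdh. Most pairs of spike-in probe sets, described below, moved opposite to these ratios. For dap the 5′ probe set fell relatively more (245 to 52.8) than the 3′ one (14800 to 5260). The same held for phe (95.9 to 12.9 and 2200 to 661). Only a thr pair moved as actin and Gapdh did (52.5 to 16.3 and 4920 to 1130). The other thr pair moved as dap and phe did (51.7 to 8.13 and 4930 to 1260).

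The age changes of the 2 sexes, which share no arrays, ran largely in parallel. Across 18193 genes the female and male log2 changes correlated with Pearson r = 0.764 and Spearman rho = 0.691, and with r = 0.786 over the 10966 genes at or above the median intensity; genes are not independent replicates, and no p is given. Of the genes that rose at least 2-fold, 1091 in females and 1082 in males, 623 rose in both, against 64.9 for independent lists. Of those that fell at least 2-fold, 1334 and 943, 654 fell in both, against 69.1. Opposite changes of at least 2-fold were seen for 2 genes that rose in females and fell in males and 1 gene that did the reverse. The poly-A spike-ins, described below, also fell with age in both sexes, by differing amounts. A probe set for the middle part of thr went from 938 to 175 in females and from 833 to 99.4 in males. A difference in preparation between the ages that the sexes share could thus add to the agreement. No test here separates it from age, so sharing no arrays does not make the 2 age changes independent.

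**Figure D2:**
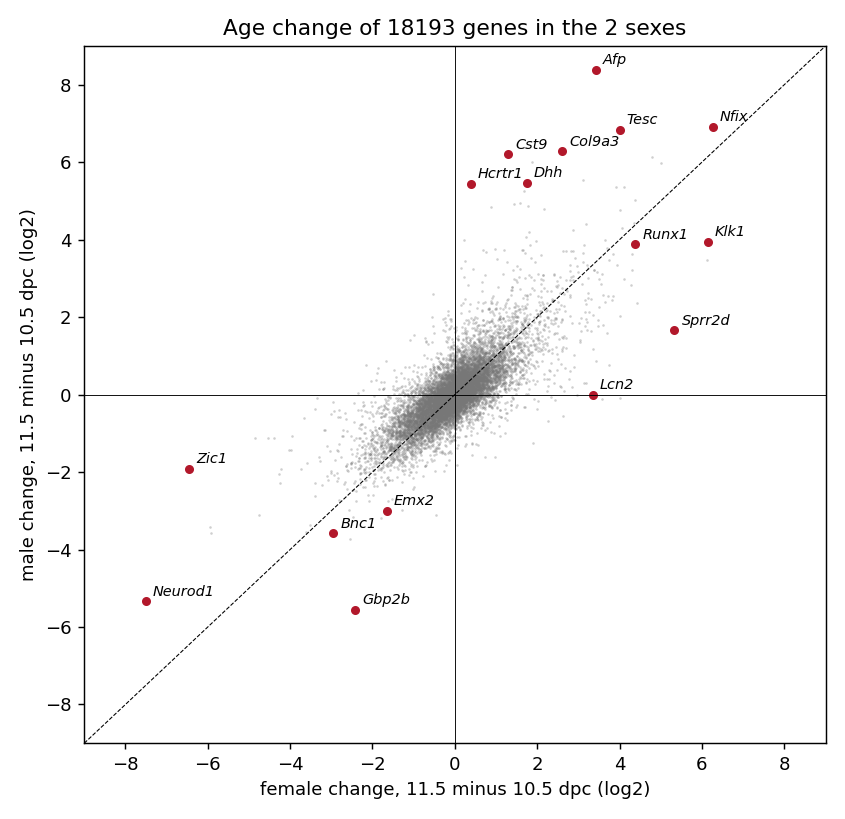
Log2 change from 10.5 to 11.5 dpc in females (horizontal axis) and in males (vertical axis) for 18193 genes, each a point, with named genes in red and equal change as the dashed line. Most genes lie along the line (r = 0.764), with Afp, Cst9 and Hcrtr1 above it and Sprr2d and Lcn2 below.

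The size of the age change differed between the sexes for testis genes, which rose more in males, and for genes of neurons, vessels and germ cells, which fell more or rose less in females. Hcrtr1 rose by 5.06 ± 0.14 more in males than in females on the log2 scale, Cst9 by 4.91 ± 0.16 more, Gdnf by 3.96 ± 0.23 more and Fgf9 by 3.05 ± 0.1 more. Of 22 testis list genes, 13 moved up and 2 down in males relative to females (14 and 3 adjusted over the list alone), with camera adjusted p = 2.4e-05. Of 20 ovary list genes, 12 moved down and 2 up (12 and 2 adjusted over the list alone, camera adjusted p = 0.0019), with Sprr2d at -3.67 ± 0.18 and Wnt4 at -1.66 ± 0.07. Lgr5 moved up by 2.93 ± 0.18.

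Endothelial, germ cell and neural genes moved up in males relative to females. Of 15 endothelial genes 10 moved up and none down (10 and 0 adjusted over the list alone, camera adjusted p = 8.6e-05). Of 17 germ cell genes 11 moved up and none down (11 and 0 adjusted over the list alone, camera adjusted p = 4.2e-05). Of 12 neural genes 7 moved up and none down (8 and 0 adjusted over the list alone, camera adjusted p = 0.00013). Kdr, a receptor of vessel growth, stood at 1.42 ± 0.13, Sox2 at 2.87 ± 0.1 and Tubb3 at 3.28 ± 0.17. These 3 lists were also higher in females than in males at 10.5 dpc. At 11.5 dpc the germ cell, endothelial and neural lists did not pass between the sexes (camera adjusted p = 0.12, 0.58 and 0.59). Their difference in age change thus rests mostly on the levels at 10.5 dpc. Females at 10.5 dpc had the lowest actin 3′ to 5′ ratio of the 4 groups, 5.32. The other lists of other cell types did not pass: erythroid cells (camera adjusted p = 0.2), macrophages (0.46), nephric duct (0.9), skeletal muscle (0.18) and coelomic epithelium (0.53).

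Cell division and signalling genes differed too. Of 21 cell cycle genes, 18 moved up in males relative to females and none down (18 and 1 adjusted over the list alone, camera adjusted p = 4.3e-09), such as Bub1 (1.83 ± 0.092) and the G1 cyclin Ccne1 (1.06 ± 0.063). Hedgehog and Notch targets moved up in 8 and down in 1 of 14 cases (9 and 1 adjusted over the list alone, camera adjusted p = 0.0042), with Jag1 at 1.13 ± 0.069 and Ptch1 at 0.83 ± 0.1. FGF targets moved up in 4 of 8 cases with none down (4 and 0 adjusted over the list alone, camera adjusted p = 0.014). Their list had an adjusted p = 0.11 with an estimated correlation, and Etv5 stood at 2.81 ± 0.11. Genital ridge factors moved down in 8 and up in 2 of 16 cases (9 and 3 adjusted over the list alone, camera adjusted p = 0.01), with Emx2 at -1.34 ± 0.055 and Lhx9 at -1.15 ± 0.04. They had an adjusted p = 0.1 with an estimated correlation. Sox9 moved up by 1.35 ± 0.18. Retinoic acid genes (6 of 12 up, 2 down, 6 and 2 adjusted over the list alone) had camera adjusted p = 0.044, and an adjusted p = 0.11 with an estimated correlation. Cholesterol synthesis genes (7 of 15 up, 2 down, 8 and 2 adjusted over the list alone) had camera adjusted p = 0.041, and an adjusted p = 0.1 with an estimated correlation. Immediate early genes (7 of 15 up, 2 down, 7 and 2 adjusted over the list alone) had camera adjusted p = 0.04, and an adjusted p = 0.28 with an estimated correlation.

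The test called 12640 probe sets for this difference, 6585 up and 6055 down in males relative to females. In genes 3420 moved up and 2731 down, with 563 genes up and 337 down by at least 2-fold. The testis, ovary, germ cell, endothelial, neural, cell cycle and hedgehog and Notch lists passed with an estimated correlation (adjusted p from 0.014 to 0.032). In each comparison, the lists that passed had a median, a mean and a test of the same sign.

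**Figure D3:**
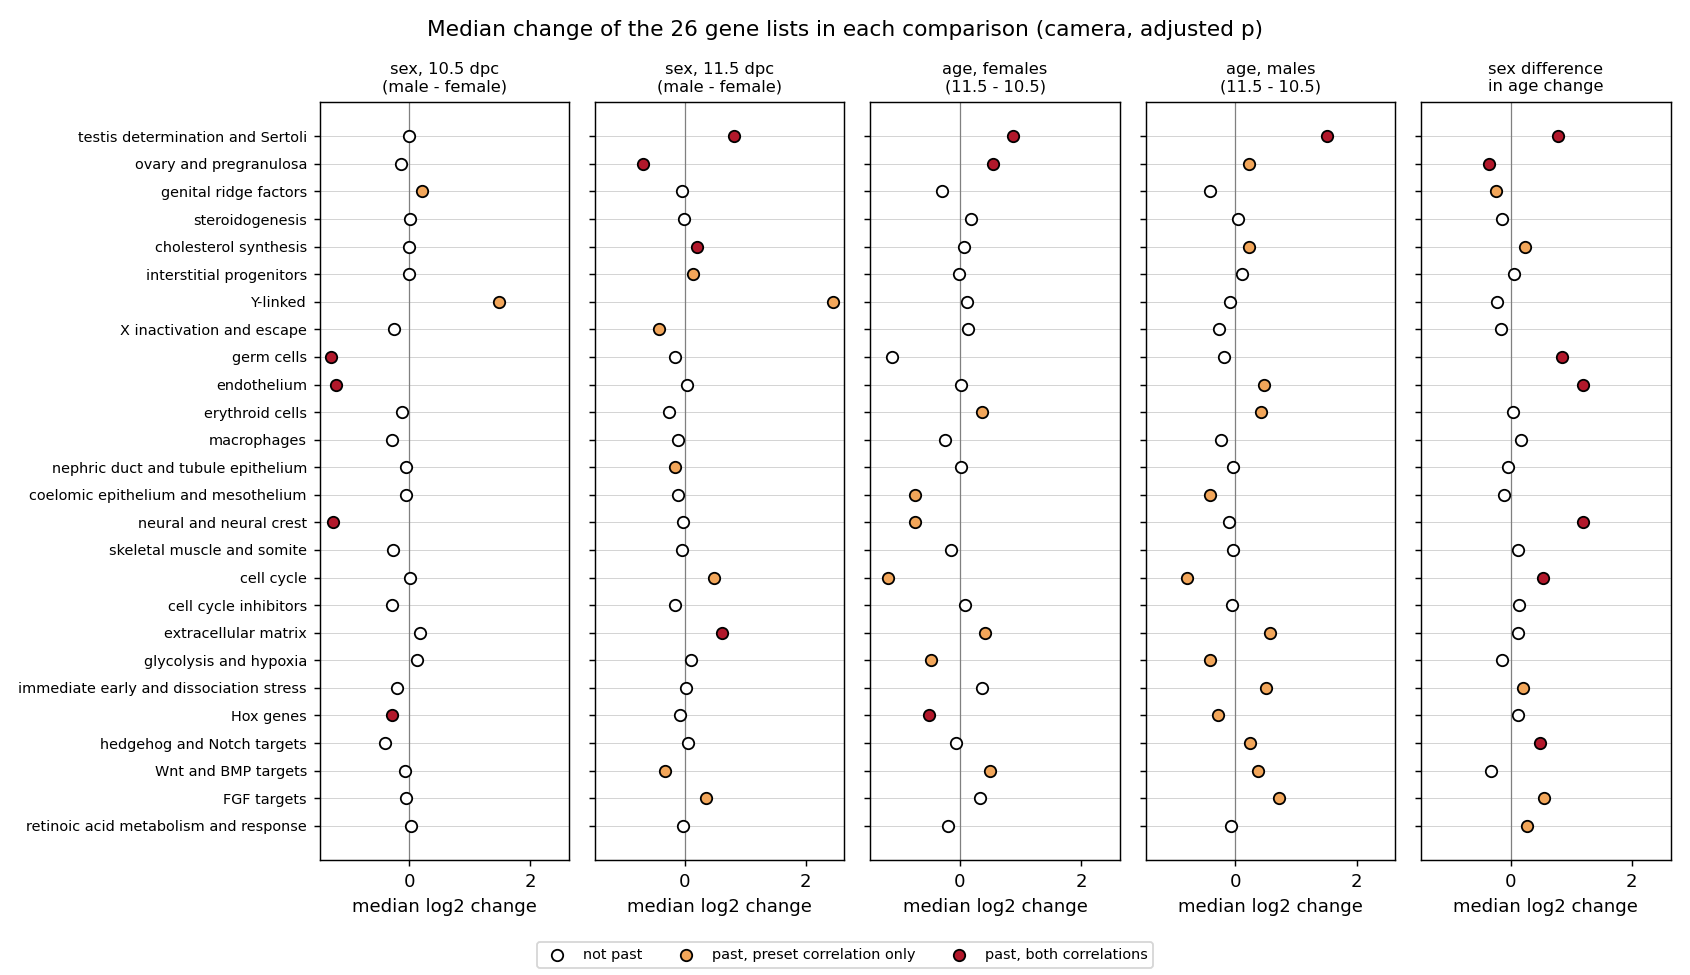
Median log2 change (horizontal axis) of the measured genes of each of the 26 lists (vertical axis) in the 5 comparisons; white points did not pass camera, orange points passed with the preset correlation only and red points with both correlations. The testis list lies at 0 in the sex difference at 10.5 dpc and at 0.81 at 11.5 dpc, the ovary list at -0.13 and -0.69.

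The control probe sets were read apart from these comparisons. The 24 probe sets of the poly-A spike-ins, bacterial transcripts that are mixed into the RNA before amplification, had a median SD within groups of 0.0747 and between group means of 1.29 on the log2 scale. The 18 probe sets of the hybridisation controls, which are mixed in just before each array is incubated, had a median SD within groups of 0.553. One spike-in probe set, for the 5′ part of dap, had mean intensities of 446 ± 25 (SD, n = 3) in females and 245 ± 4.68 in males at 10.5 dpc, and of 248 ± 7.55 in females and 52.8 ± 0.379 in males at 11.5 dpc.

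**Figure D4:**
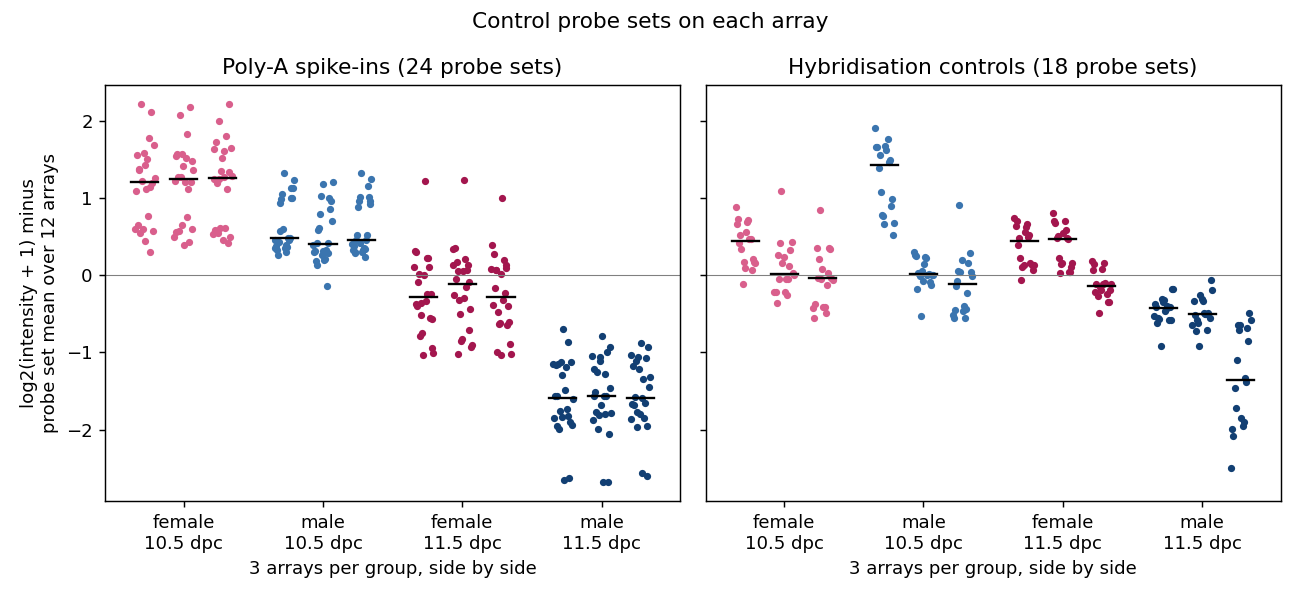
Level of each poly-A spike-in probe set (left) and hybridisation control probe set (right) on each of the 12 arrays, as log2(intensity + 1) minus the probe set's mean over all arrays (vertical axis); black lines are array medians, and the 3 arrays of a group stand side by side. Spike-ins lie at about the same place on the arrays of a group (median SD 0.0747) and differ between groups (1.29), while hybridisation controls differ within groups (0.553).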

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

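The tests of the spike-ins, of the other cell type lists, of the 5′ signal and of Eif2s3y were chosen only after the results were seen; the test of stage and the counts of other splits were planned.

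The age change differed between the sexes, by a test of the difference itself, for 12640 probe sets. Of 100 groupings of the 12 arrays into 4 groups of 3, the real one included, only the real 1 gave as many, and the highest other gave 8778. Of the 99 others 85 gave 0: such splits mix unlike arrays, which widens the spread within groups and favours the real one, so its rank does not exclude chance differences between preparations. For the other counts the 10 possible splits of 3 against 3 arrays are too few for a share under 0.05, and 1 of the 10, the real split, gave as many probe sets each time. Between the sexes the real split gave 15371 at 10.5 dpc (highest other 2) and 15522 at 11.5 dpc (highest other 1). For the age change it gave 18800 in females (highest other 1) and 21040 in males (highest other 0). The other splits here mix unlike arrays too, so their low counts do not exclude chance differences between preparations.

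Single genes with the largest differences in age change were Hcrtr1 (5.06), Afp (4.97), Cst9 (4.91), Zic1 (4.54), Mapk13 (4.13), Gdnf (3.96), AU015836 (3.77), Hmx1 (3.74), Dhh (3.73) and Col9a3 (3.68), all upward in males relative to females on the log2 scale. Downward were Ugt2b36 (-4.09), Taf7l (-3.69), Sprr2d (-3.67), Lcn2 (-3.35), Eif2s3y (-3.18), Morn1 (-3.14), Gbp2b (-3.13), Slitrk1 (-2.98), Tph2 (-2.97) and 4930563E18Rik (-2.95). Zic1 had a mean intensity of 598 in females and 31 in males at 10.5 dpc, and of 5.91 and 6.49 at 11.5 dpc, near the lowest intensities.

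Gene lists that passed camera for the difference in age change, given with their medians, were testis determination and Sertoli (0.78), ovary and pregranulosa (-0.36), genital ridge factors (-0.24), cholesterol synthesis (0.24), germ cells (0.84), endothelium (1.19), neural and neural crest (1.19), cell cycle (0.54), immediate early and dissociation stress (0.21), hedgehog and Notch targets (0.49), FGF targets (0.55) and retinoic acid metabolism and response (0.27). With an estimated correlation 5 of these did not pass: genital ridge factors (adjusted p = 0.1), cholesterol synthesis (adjusted p = 0.1), immediate early (adjusted p = 0.28), FGF targets (adjusted p = 0.11) and retinoic acid (adjusted p = 0.11).

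The poly-A spike-ins, which no comparison used, differed between groups with a median SD of 1.29 on the log2 scale and hardly within groups. Their within-group SD was 0.964 times that of ordinary probe sets of like level, while the hybridisation controls had 7.14 times that SD. A candidate explanation is that the 3 arrays of a group carried 1 shared amplified RNA, and the ratio of 0.964 is what that would give. Separate preparations made side by side with equal doses stay open: the spike-ins varied 17.3 times as much between groups as within, and no value here separates these readings. Under the first reading, a difference between groups cannot be told apart from a difference between single preparations.

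Genes of neurons, germ cells and vessels were higher in females than in males at 10.5 dpc, while Nr5a1 (0.73), Gata4 (1) and 10 of 16 genital ridge factors (camera adjusted p = 0.015, adjusted p = 0.12 with an estimated correlation) were higher in males. A lower share of gonadal cells in the female preparation would raise every other cell type alike. Over genes at or above the median intensity in females at 10.5 dpc, the 7 lists with 5 or more such genes had medians up to 1.67 ± 0.51 apart. They ran from -1.62 ± 0.42 (neural) to 0.05 (coelomic epithelium), and 4 erythroid genes had -2.26. These SE are over genes, which are not replicates. Coelomic genes such as Bnc1 (1580 in females, 1630 in males) were as high in males and may belong to the sorted cells. Macrophage (-0.18 ± 0.17) and muscle (-0.37 ± 0.27) genes also moved less than neural ones. Lists that stay flat may be expressed by the sorted cells or stem from cells absent from both samples. The spread of the medians therefore does not decide on an equal rise of every other cell type. A lower share of gonadal cells stays open, whether it raises all or only some cell types, although the sort is meant to remove other cells. The spike-ins too had relatively less 5′ signal in males than in females at 10.5 dpc, in each pair of 3′ and 5′ probe sets. For phe the 5′ probe set read 235 in females and 95.9 in males, and the 3′ one 2190 and 2200. Whether this loss of 5′ signal accounts for the lists stays open, since the females at 11.5 dpc differ in age too. Their actin ratio was as high as in males at 10.5 dpc (9.97 and 9.9), but their Gapdh ratio was lower (3.88 and 4.65). From 10.5 dpc the median change in females was 0.02 for endothelial genes, with Emcn at -2.03 and Plvap at 0.49. For neural and germ cell genes it was -0.98. A younger stage of the female embryos predicts that genes at least 2-fold lower in males at 10.5 dpc fall with age in males. With array 1, 2 or 3 used to choose them, 410, 504 and 449 genes of any kind had median male changes of 0.33, 0.3 and 0.36. Their SE over genes, which are not replicates, were 0.068, 0.063 and 0.062, and only the third lay over 2 SE above the bound of 0.2. Genes chosen as low in males at 10.5 dpc, with a call from all 3 arrays, lean towards a rise, so the sign does not decide. The neural, germ cell and endothelial lists had male medians of -0.1, -0.18 and 0.48. A younger stage stays open, as does a sex difference of the cells themselves.

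Eif2s3y, a Y-linked gene, stood at 64.7 in females at 11.5 dpc. Cross-hybridisation of its X-linked copy is argued against by Eif2s3x, which changed by -1.14 in females over the same day. Male cells or RNA carried into the female samples would need a share of 3.44% (SD 0.3); Cst9 allowed a share of up to 2.19% (SD 0.69), less than 2 SD below it, so this cannot be told apart from other sources. Gdnf gave 3.2% (SD 1.8), which would allow it, while Hcrtr1 gave 0.74% (SD 0.54), Uty 0.272% (SD 0.5) and Kdm5d 0.32% (SD 0.56), all 3 near the lowest intensities in females, where fold changes are understated. The other Eif2s3y probe set read 3.05 and 3.02 on the log2 scale in females at 10.5 and 11.5 dpc. In males it read only 4 and 3.97, so a small share of male signal could not be seen on it.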

How the results depend on the processing

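The split of the arrays by hybridisation controls and Fisher's exact test were chosen after seeing the data. The counts of calls stayed within 1.5 times the main count under the filter, both other normalizations, other eBayes settings, array weights, other probe set choices, the pseudocount of 16 and an adjusted p under 0.01. With the replicate number as a block they were 15076, 15174, 18568, 20174 and 12184 in the order of the comparisons (sexes at 10.5 and 11.5 dpc, age in females and males, difference of age changes). The numbers did not pair the arrays: in 18 same-numbered pairs the deviations correlated with r from -0.107 to 0.0628, and 0 pairs were over 0.1. Counted in genes, with probe sets averaged, the calls were 7318, 7278, 9196, 10147 and 6051, which follows from fewer features tested; with a change of at least 2-fold also asked they were 1813, 1487, 4881, 4003 and 1981. In the 8 arrays of the larger control set, where females at 10.5 dpc have 1 array assumed to vary like the others, the difference of age changes had 8399 calls, with fewer samples. With the array set as a block, 1812 of 1813, 1486 of 1487, 4870 of 4881, 4003 of 4003 and 1945 of 1981 probe sets changed at least 2-fold kept call and direction. Leaving out each array gave 14211 to 15285, 13841 to 15507, 17719 to 18753, 18027 to 21876 and 11518 to 12475 calls. Of 130 list tests 53 passed camera, 19 with an estimated correlation, 121 with fry (which does not compare a list with other genes), 26 with Fisher's exact test (21 of them among the 53), 56 with the replicate block (51 among the 53) and 51 to 57 without single arrays; the cause of these moves was not tested. The correlation of the age changes was 0.778 with the filter and 0.759 to 0.765 without single arrays. Of 10517 alternative values for named genes, 10430 kept their side of the threshold, and also their direction where the main fit had passed. Direction was not checked for values that did not pass in the main fit. Of the rest 78 lost the call, 4 gained it and 5 reversed, all 5 when the probe sets of a gene were averaged. These were Lss (-0.13) and Hmgcs1 (-0.35) in females with age, Vegfa (0.19) in males with age, and Stard4 (-0.01) and Nr2f2 (-0.31) for the difference of age changes. Their probe sets disagree.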

Other observations

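The genes in this part were chosen after their values were seen, and no further test was run on them. Some genes of vessels and blood had their lowest levels in males at 10.5 dpc. The endothelial transcription factor Erg had mean intensities of 271 in females and 59.4 in males at 10.5 dpc, and of 311 and 300 at 11.5 dpc. The vessel surface protein Cd34 had 105 and 15.8 at 10.5 dpc, and 126 and 167 at 11.5 dpc. Hbb-y, an embryonic globin, had 2260 and 288 at 10.5 dpc, and 7340 and 3640 at 11.5 dpc. The endothelial gene Emcn differed from these, with 86.8 in females at 10.5 dpc and 20.4 to 25.6 in the other 3 groups.

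Some genes of the germ cell list had their highest levels in females at 10.5 dpc. Sox2 had mean intensities of 1930 in females and 204 in males at 10.5 dpc, and of 124 and 95.7 at 11.5 dpc. Pou5f1 had 222 and 41.7 at 10.5 dpc, and 45.9 and 36.3 at 11.5 dpc. Not every germ cell gene had this course: Dazl, an RNA-binding protein of germ cells, had 42.4 and 25.2 at 10.5 dpc, and 170 and 102 at 11.5 dpc.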
